A study of Homo sapiens with 4 samples.

How the data were processed

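Gene expression was measured by RNA sequencing in a cell line that the labels give as human lung squamous cell carcinoma. Its identity was not tested here. The 4 libraries fall into 2 groups of 2 by the dose in their library names, 0 Gy and 30 Gy (gray, the unit of absorbed radiation dose), each with replicates numbered 1 and 2. RNA was extracted with Trizol, and 0.2 ug of total RNA per library entered an Illumina library preparation, per the labels' protocols. The series' design text names SK-MES-1 cells and a radiotherapy-resistant derivative, SK-MES-1-RR. The labels do not say which libraries came from which of these lines, whether the 30 Gy were given at one time or in fractions, or how long after irradiation RNA was taken. The groups are therefore called 0 Gy and 30 Gy throughout. Nothing states that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

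The authors deposited a single table of FPKM values (fragments per kilobase of gene, scaled to library size) for 58735 genes in the 4 libraries, with gene identifiers, names, positions and lengths. The genome build was hg38, per the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here. All 58735 gene identifiers, positions and names matched GENCODE v29 on GRCh38, the annotation used here for transcripts and GC content. In every library, FPKM multiplied by the deposited gene length was a whole multiple of a library-specific step for 100% of the values above 0, within a tolerance of 0.001. Whole reads per gene were recovered in this way, and their totals were 17261121 and 16773381 in the 0 Gy libraries and 15920861 and 15979341 in the 30 Gy libraries. The divisor behind the deposited FPKM was 0.996 to 1.01 times these totals, so the authors' library total was not exactly the sum over the listed genes. The reads serve for depth, for detection floors (3 reads) and for an alternative test. Floors cover counting error only.

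The design was fixed before the data were examined. Genes with an FPKM of at least 1 in at least 2 libraries were tested (13379 genes) with limma (lmFit and eBayes with trend, two-sided) on log2(FPKM + 1), with no further scaling, no covariate, and Benjamini-Hochberg adjustment at 0.05. All log2 changes are 30 Gy minus 0 Gy on this scale, which understates the change of genes with low FPKM. Fold differences given for single genes are ratios of mean FPKM. Counts of genes changed at least 2-fold use the log2 change of the fit instead. The fit had 2 residual degrees of freedom and a prior of 2.98. A permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333, so no such test is used. Before the data were examined, 38 gene lists were also fixed. The 28 with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. With a correlation estimated per list, camera falls back on the 2 residual degrees of freedom, and no list passes. fry tests whether a list's genes move one way on balance and compares the list with no other genes. Each member is also given adjusted over the list alone.

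The named genes follow a rule written in advance. They are KRT6A and RAB39B, which the series title names, then the 12 largest rises and 12 largest falls among protein-coding genes past the threshold with a mean FPKM of at least 5 in the higher group and groups that do not overlap, then up to 4 members of each list past the threshold (up to 2 if none passes). Other genes are named where stated, or to complete a count. Some genes that meet the rule are not reported here.

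On simulated reads drawn from the real means and totals (13328 genes in the step, 65 changed genes at each fold size), limma on log2(FPKM + 1) recovered 7.69% of genes changed 1.5-fold, 70.8% of genes changed 2-fold and 92.3% of genes changed 4-fold. It also called 24 unchanged genes, 17.8% of its calls, above the nominal rate. With nothing changed it called 0 genes. limma's voom on the simulated reads recovered 56.9%, 90.8% and 93.8%, with 2.48% of its calls on unchanged genes. Every simulated gene had the same dispersion, 0.00697, so these rates need not hold for the real genes. When 1 list was moved, camera called that list and no other. Genes were simulated independently, so this cannot show how often camera calls unchanged lists whose genes vary together. Given the 17.8% of calls on unchanged genes, values near the threshold in the main test are less certain than the adjusted p says.

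Alternatives planned in advance were another pseudocount (0.1), no filter and a filter at FPKM 5, median centring, quantile normalization, rescaling to equal sums, eBayes without trend or with robust, a replicate block, and each library left out. Added after the data were seen were voom on the recovered reads, removal of each library's trend on GC content and gene length, protein-coding genes alone, rescaling without mitochondrial genes, and leaving out a region of chromosome 11. The planned count-based test was not run, because the table holds FPKM. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.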

Results

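RNA from a cell line labelled as human lung squamous carcinoma was sequenced at 0 Gy and at 30 Gy, with 2 libraries per dose. The series title places the work in radiotherapy resistance and names KRT6A, a keratin of stratified epithelium, the autophagy pathway, and RAB39B, a small GTPase of vesicle traffic. The recovered depth was 15920861 to 17261121 reads per library. Libraries of the same group were closer to each other than libraries of different groups. Pearson's r of log2(FPKM + 1) over the 13379 tested genes was 0.984 between the 0 Gy libraries and 0.981 between the 30 Gy libraries, against 0.956 to 0.958 between groups. The median absolute log2 difference was 0.0984 and 0.111 within groups and 0.218 to 0.224 between them. Replicates differed by more than sampling noise, with a mean chi-square per gene of 5.66 and 5.26, so none is a copy of another.

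Compared with the 0 Gy libraries, the 30 Gy libraries had higher expression of mesenchymal genes and of cell division genes, and lower expression of NRF2 target genes, which serve antioxidant defence. TGFBI, a secreted matrix protein induced by TGF-beta, stood at 50.7 ± 0.255 FPKM at 0 Gy and 292 ± 3.23 at 30 Gy (SD, n = 2 each). GCLC, which catalyses the first step of glutathione synthesis, fell from 125 ± 4.66 to 40.6 ± 0.829. KIF20A, a kinesin of cell division, rose from 14.1 ± 0.484 to 27.5 ± 0.0680. Of 24 tested genes on the mesenchymal list 17 rose and 1 fell, of 30 on the G2 and M-phase list 25 rose and 0 fell, and of 28 NRF2 targets 1 rose and 22 fell. These 3 lists passed camera at the preset correlation and not with an estimated correlation (adjusted p = 0.386, 0.386 and 0.384 with an estimated correlation).

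limma called 2654 of the 13379 genes at an adjusted p under 0.05, with 1442 higher and 1212 lower at 30 Gy. On the log2(FPKM + 1) scale, 347 of these changed at least 2-fold, 202 higher and 145 lower. Genes with low FPKM can exceed 2-fold by the ratio of means and still be outside this count, such as RAB39B (2.45-fold lower). At an unadjusted p under 0.05 there were 5049 genes. The 2 groups did not overlap for 65.2% of the tested genes, where chance gives 33.3%. Without either 0 Gy library, which leaves that group with a lone library, 0 genes passed (3422 and 3460 at an unadjusted p under 0.05); without the first or second 30 Gy library 898 and 862 passed. voom on the recovered reads called 4231 genes, 2498 of them shared with the main test and all of those in the same direction, while testing every gene above 0 called 604.

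Among the 12 largest rises by the naming rule, CGB5, a chorionic gonadotropin beta gene at 19:49043884-49045311 (hg38), rose from 11.8 ± 1.17 to 124 ± 9.45 FPKM, and its neighbour CGB8 from 4.38 ± 0.0669 to 26.0 ± 2.78. These genes and CST1, a salivary cystatin that rose from 1.36 ± 0.213 to 17.2 ± 1.93, have near-identical relatives, so the split of reads between copies is uncertain. AMTN, an enamel matrix protein, rose from 0.558 ± 0.308 to 12.5 ± 0.0737, and PLPP4, a lipid phosphatase, from 0.748 ± 0.0797 to 10.6 ± 0.198. IL11, a cytokine of the IL-6 family, rose from 0.468 ± 0.0232 to 8.70 ± 0.603, and TXNIP, which binds and inhibits thioredoxin, from 0.794 ± 0.0246 to 9.20 ± 1.09. TPM1, an actin-binding tropomyosin, rose 6.19-fold to 53.2 ± 1.19. PMEPA1, a TGF-beta-induced regulator of SMAD signalling, rose 5.88-fold to 96.1 ± 0.806. CTGF, the matricellular protein also named CCN2, rose 5.41-fold to 111 ± 2.06. KRT17 and TGFBI completed the 12, whose adjusted p ran from 0.000447 (TGFBI, TPM1, PMEPA1 and CTGF) to 0.00179 (KRT17).

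Among the largest falls by the naming rule, PNMA5, a member of the paraneoplastic antigen family at X:152988824-152994127, fell from 82.6 ± 2.63 to 5.16 ± 0.219 FPKM, a log2 change of -3.76 ± 0.07 (SE, adjusted p = 0.000420). GPNMB, a lysosomal and melanosomal glycoprotein, fell from 18.5 ± 0.148 to 3.05 ± 0.0733. NR0B1, an orphan nuclear receptor, fell from 84.3 ± 3.82 to 19.3 ± 2.03. DDIT4, an inhibitor of mTORC1, fell 4.11-fold from 49.3 ± 2.50, and GDF15, a stress-induced cytokine, from 93.0 ± 3.61 to 25.5 ± 3.06. OSGIN1 fell from 38.3 ± 2.59 to 9.23 ± 0.465, and RAP1GAP, which switches off the GTPase RAP1, from 21.7 ± 0.246 to 5.10 ± 0.936. TNFRSF18, a receptor of the TNF family, fell 5.01-fold. NCR3LG1, a ligand of the NK-cell receptor NKp30, fell from 8.11 ± 0.256 to 1.70 ± 0.203, and DKK3, a secreted protein of the dickkopf family, from 67.4 ± 1.89 to 22.1 ± 0.726. NCR3LG1 lies inside a stretch of chromosome 11 in which neighbouring genes fell together, and DKK3 lies 11.96 Mb along the same chromosome, just before that stretch. GCLC, given above, was also among the largest falls.

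**Figure D1:**
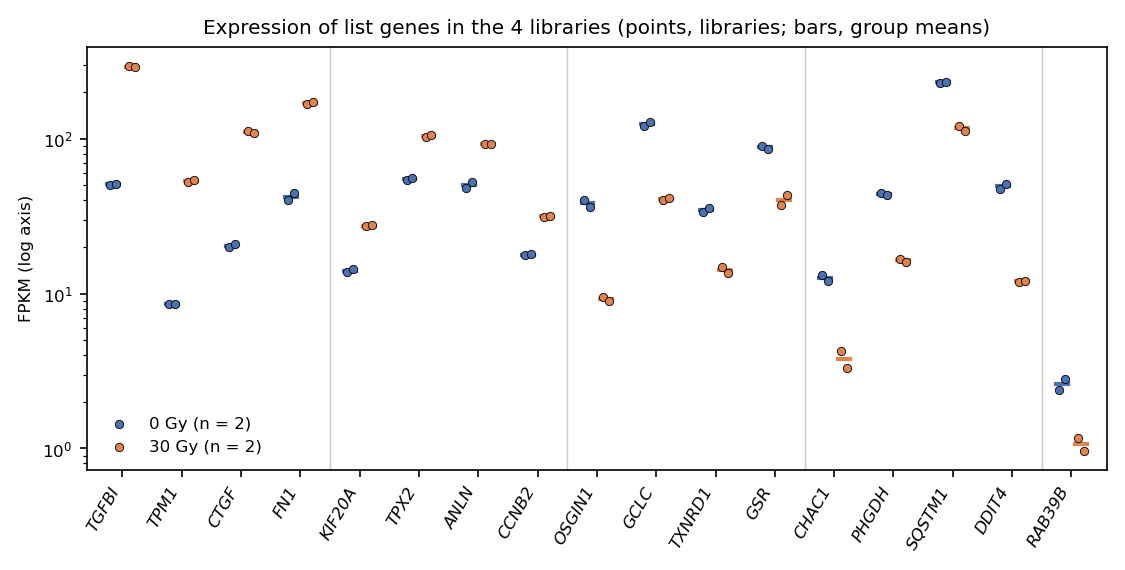
FPKM per library (y axis, log scale) of mesenchymal, cell division, NRF2 target and stress or autophagy genes and of RAB39B (x axis, divided by grey lines in that order); points are libraries, 2 per dose, and bars are group means. The points of the 2 doses do not overlap for any gene shown: TGFBI stands near 50.7 at 0 Gy and 292 at 30 Gy, GCLC near 125 and 40.6.

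Mesenchymal genes were higher as a group at 30 Gy. FN1, fibronectin, rose from 42.2 ± 3.01 to 171 ± 2.14 FPKM, and VIM, the mesenchymal intermediate filament vimentin, from 226 ± 16.3 to 507 ± 5.78. The transcription factor SNAI1 rose by 1.16 ± 0.15 (SE, log2) and ZEB1 by 0.38, whereas TWIST1 changed by -0.39 (adjusted p = 0.0435). The list's median log2 change was 0.85, and camera gave an adjusted p of 1.25e-08 (adjusted p = 0.386 with an estimated correlation). Adjusted over the list alone, 17 members rose and 2 fell. The fibroblast markers PDGFRB (2.16-fold) and COL1A1 (1.17-fold) were also higher at 30 Gy, without passing the test over all genes. Of 14 tested collagens 4 rose and 0 fell (4 and 0 adjusted over the list alone): COL4A1 (2.50-fold), COL7A1 (2.33-fold), COL4A2 (1.82-fold) and COL5A1 (1.73-fold). The collagen list did not pass (adjusted p = 0.0686), though it did at a filter of FPKM 5 (0.0242), with voom (0.0231), with the GC and length trends removed (0.0221) and without the second 30 Gy library (0.0331).

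Epithelial junction and squamous lineage genes did not pass as groups. Of 10 junction genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.179): LSR and CLDN1 fell, by 0.82 and 0.55 on the log2 scale, and TJP1 rose by 0.35. CDH1, E-cadherin, had 0 to 7 reads per library and was not tested. Of 15 basal and squamous lineage genes 5 rose and 3 fell (6 and 6 adjusted over the list alone; adjusted p = 0.708). LAMB3, a laminin chain, rose from 89.2 ± 1.91 to 127 ± 6.86, while LAMA3 fell from 11.6 ± 0.305 to 7.31 ± 0.245. DSP, desmoplakin, fell by 0.94 on the log2 scale. TP63, the squamous lineage factor, stood at 4.04 ± 0.128 and 3.26 ± 0.105 and did not pass. Of 4 tested cornified envelope genes, PPL (periplakin, 2.81-fold to 8.90 ± 0.284) and FLG (filaggrin, 1.18 ± 0.0552 to 0.347 ± 0.00262) fell and 0 rose (0 rose and 3 fell adjusted over the list alone).

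KRT6A (ENSG00000205420, 12:52487174-52493257, minus strand), the gene the title names, was listed at 0 reads in all 4 libraries. At these depths 3 reads would equal 0.0589 to 0.0644 FPKM, so any expression lay below that and no change between doses was detectable. KRT5, KRT6B and KRT6C were at 0 reads in the 4 libraries too, and KRT14, the usual partner of KRT5, had 0 to 4 reads. KRT17, a stress-inducible keratin, was the member of the stratified keratin list that rose, from 0.158 ± 0.0420 to 6.06 ± 0.906 FPKM; of the 3 tested members KRT10 and KRT80 did not pass (1 rose and 0 fell adjusted over the list alone). The keratins of simple epithelium were abundant. KRT7 rose from 95.8 ± 0.615 to 211 ± 14.2 and KRT19 fell from 162 ± 4.27 to 88.4 ± 6.18, while KRT8 (38.4 and 42.5) and KRT18 (37.1 and 40.0) did not pass, giving 1 rise and 1 fall among 4 tested genes, also when adjusted over the list alone.

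**Figure D2:**
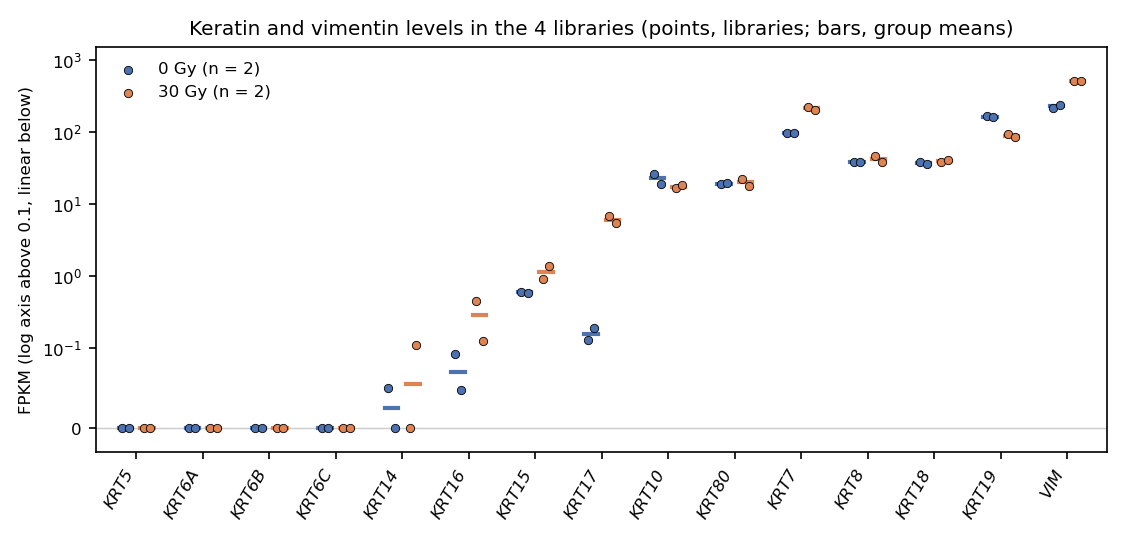
FPKM per library (y axis, log above 0.1 and linear below) of keratins and vimentin (x axis); points are libraries, 2 per dose, and bars are group means. KRT5, KRT6A, KRT6B and KRT6C are at 0 in all 4 libraries, KRT17 is near 0.158 at 0 Gy and 6.06 at 30 Gy, and KRT7, KRT8, KRT18 and KRT19 lie above 30 in every library.

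RAB39B (ENSG00000155961, X:155258241-155264589, minus strand), the other gene of the title, was lower at 30 Gy. It stood at 2.61 ± 0.301 FPKM at 0 Gy (146 and 168 reads) and 1.07 ± 0.137 at 30 Gy (65 and 54 reads), a log2 change of -0.80 ± 0.13 (SE) with an adjusted p of 0.0190. RAB39A, its closest relative, had 0 reads in each library. The call on RAB39B was lost when every gene above 0 was tested (adjusted p = 0.0919) and when any library was left out, though the change stayed between -0.89 and -0.72. Its adjusted p was 0.0583 and 0.0690 without the first and second 30 Gy library, and 0.108 and 0.129 without the first and second 0 Gy library, where no gene at all passed; voom gave -1.30 with an adjusted p of 0.00104. Among 44 tested RAB GTPases 1 rose and 4 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.711): RAB29, RAB12 and RAB7A, a regulator of late endosomes, fell by 0.45, 0.41 and 0.39 on the log2 scale, and RAB5B rose by 0.27.

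Autophagy genes were tested as core machinery and, apart from it, as receptors and regulators. Of 35 core genes 3 rose and 1 fell, the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.382). GABARAPL1 rose from 7.87 ± 0.644 to 13.3 ± 0.641 FPKM, MAP1LC3B, which encodes an LC3 protein of autophagosome membranes, from 7.72 ± 0.717 to 11.7 ± 1.31, and RB1CC1 from 13.3 ± 0.556 to 16.8 ± 0.246; GABARAPL2 fell 1.26-fold. Of 30 receptors and regulators 1 rose and 7 fell (1 and 8 adjusted over the list alone; median -0.12; camera adjusted p = 0.0285, and adjusted p = 0.517 with an estimated correlation). SQSTM1, the cargo receptor p62, fell from 232 ± 2.20 to 117 ± 5.07, SESN2 from 14.6 ± 0.270 to 6.03 ± 0.221 and PRKAA2, a catalytic subunit of AMPK, 1.61-fold, and OPTN rose by 0.48 on the log2 scale. DDIT4 and SESN2, at the top of the falls, inhibit mTORC1, and SQSTM1 is also a known NRF2 target. The list missed the threshold without the second 0 Gy library (0.0621) and without the first 30 Gy library (0.0519).

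Lysosome genes were lower as a group. Of 33 tested genes 2 rose and 12 fell (3 and 18 adjusted over the list alone), with a median log2 change of -0.22 and a camera adjusted p of 0.000827 (adjusted p = 0.517 with an estimated correlation). CTSH, a cathepsin, fell from 10.8 ± 0.540 to 4.87 ± 0.349 FPKM, LAMP3 from 1.65 ± 0.114 to 0.444 ± 0.117, NPC1, a cholesterol transporter, from 29.8 ± 0.818 to 17.7 ± 1.07, and CTSA from 78.2 ± 0.770 to 50.6 ± 3.44.

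NRF2 target genes showed the largest fall of any tested list. Besides OSGIN1 and GCLC, TXNRD1, thioredoxin reductase, fell from 34.6 ± 1.21 to 14.2 ± 0.944 FPKM and GSR, glutathione reductase, from 88.2 ± 3.05 to 40.4 ± 3.95. NQO1, a quinone reductase, fell by 1.08 ± 0.06 (SE, log2) from a mean of 673 to 317, and PGD of the pentose phosphate pathway fell by 0.72. FTL, the ferritin light chain, fell from a mean of 7922 to 4583. AKR1C2 rose by 0.54, while HMOX1, GCLM and SLC7A11 did not pass, with log2 changes of -0.23, -0.26 and -0.04. The list median was -0.72 and the camera adjusted p 1.80e-13 (adjusted p = 0.384 with an estimated correlation); adjusted over the list alone, 1 rose and 25 fell. Some of the 14 tested ABC transporters are NRF2 targets too: ABCC1 and ABCC3 fell by 0.83 and 0.59, ABCG1 and ABCA1 rose by 0.71 and 0.57, and in all 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.270).

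Cell division genes were higher at 30 Gy. TPX2, a spindle assembly factor, rose from 55.2 ± 1.43 to 104 ± 3.06 FPKM, ANLN, a cytokinesis protein, from 50.5 ± 3.44 to 92.4 ± 0.280, and CCNB2, a mitotic cyclin, from 17.9 ± 0.269 to 31.6 ± 0.379. The G2 and M-phase list had a median log2 change of 0.52 and a camera adjusted p of 1.22e-14 (adjusted p = 0.386 with an estimated correlation), and adjusted over the list alone all 30 members rose. Of 30 S-phase genes 13 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.37; camera adjusted p = 5.70e-05, and adjusted p = 0.386 with an estimated correlation). RRM2, of ribonucleotide reductase, rose from 12.4 ± 0.887 to 23.5 ± 0.483, CDC6 from 7.73 ± 0.173 to 13.4 ± 0.310, FEN1 from 21.9 ± 0.946 to 34.4 ± 2.69 and CLSPN from 4.49 ± 0.0316 to 7.35 ± 0.818. The S-phase gene that fell, E2F8, lies in the chromosome 11 stretch.

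DNA repair and p53 lists did not pass as groups. Of 31 homologous recombination and Fanconi anaemia genes 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0686, 0.0465 at a filter of FPKM 5, and 0.0374 without the chromosome 11 stretch, which holds the gene that fell, FANCF). RAD51AP1 rose from 4.71 ± 0.741 to 8.81 ± 0.716 FPKM, BRIP1 1.63-fold and FANCG 1.52-fold, while FANCF fell 1.80-fold from 13.7 ± 0.176. Of 20 end-joining genes XRCC4, POLQ and XRCC5 rose by 0.43, 0.38 and 0.32 on the log2 scale and 0 fell (3 and 0 adjusted over the list alone; adjusted p = 0.232). Of 26 p53 targets 4 rose and 5 fell (8 and 7 adjusted over the list alone; adjusted p = 0.847; median -0.014, mean 0.0018, camera down). CDKN1A, the cell cycle inhibitor p21, rose by 0.79, DDB2 from 2.76 ± 0.206 to 6.87 ± 0.162 and TP53I3 from 3.01 ± 0.519 to 6.77 ± 0.847, while GDF15 and SESN2 fell. Of 27 apoptosis regulators 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.232): BIRC2, APAF1 and BCL2L1 rose by 0.68, 0.44 and 0.42, and BCL2L2 fell by 0.48.

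Stress-response genes went both ways. Of 29 genes of the unfolded protein and integrated stress response list 5 rose and 12 fell (5 and 14 adjusted over the list alone; median -0.24; camera adjusted p = 0.0285, 0.0512 at a filter of FPKM 5, and adjusted p = 0.517 with an estimated correlation). The members that fell, singled out after their values were seen, include genes known to answer to ATF4: CHAC1, which degrades glutathione, from 12.6 ± 0.748 to 3.78 ± 0.681 FPKM, PHGDH, of serine synthesis, from 44.0 ± 0.708 to 16.5 ± 0.532 and SLC7A5, an amino acid transporter, from 86.7 ± 1.32 to 41.1 ± 3.07. The 5 that rose were the chaperones or chaperone-like proteins HSPA5, DNAJB9, HYOU1, MANF and PDIA4 of the endoplasmic reticulum, by 0.44 to 0.79 on the log2 scale. Of 19 heat shock proteins DNAJB1 rose by 0.34, and HSP90AA1, DNAJB4 and AHSA1 fell by 0.42, 0.42 and 0.40 (1 and 4 adjusted over the list alone; adjusted p = 0.847; median 0.02, mean -0.03, camera down). Of 27 glycolysis and hypoxia genes 3 rose and 10 fell (3 and 11 adjusted over the list alone; adjusted p = 0.0686, 0.0288 with voom and 0.117 without the chromosome 11 stretch). ANGPTL4 rose 2.31-fold, while LDHA fell from 398 ± 12.7 to 217 ± 7.85, ADM 2.27-fold and EGLN3 2.07-fold; LDHA lies in the chromosome 11 stretch. Of 23 cholesterol synthesis genes IDI1 rose by 0.28 and 0 fell (0 and 0 adjusted over the list alone; adjusted p = 0.847; median 0.04, mean -0.02, camera down).

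Inflammatory genes went both ways. Of 28 NF-kB targets, cytokines and senescence-associated secreted factors 9 rose and 7 fell (10 and 11 adjusted over the list alone; adjusted p = 0.847), with a median log2 change of -0.07, a mean of 0.21 and camera pointing up. IL6 rose from 0.351 ± 0.0140 to 2.41 ± 0.285 FPKM and PLAT from 2.89 ± 0.331 to 8.80 ± 0.521, whereas CXCL2 and CSF1 fell by 1.23 and 0.79 on the log2 scale. Of 34 interferon-stimulated genes 8 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0977): OASL rose from 0.420 ± 0.215 to 2.69 ± 0.0564, the RNA sensor DDX58 2.01-fold and SAMD9 1.85-fold, and IFITM2 fell 1.97-fold. Of 16 genes of MHC class I presentation CALR and PDIA3 rose by 0.46 and 0.45 and 0 fell (2 and 0 adjusted over the list alone; adjusted p = 0.382).

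Signalling lists also held members of both signs. Of 24 immediate early and AP-1 genes 7 rose and 10 fell, also adjusted over the list alone (adjusted p = 0.847; median 0.04, mean 0.02, camera down): KLF2, KLF6 and IER3 rose by 1.03, 0.89 and 0.81 on the log2 scale and ATF3 fell by 0.88. Of 17 Wnt, Notch and YAP targets 6 rose and 3 fell (7 and 4 adjusted over the list alone; adjusted p = 0.847; median -0.15, mean 0.08, camera up): CTGF and CYR61, both YAP targets, rose and JAG2 and AJUBA fell by 1.31 and 0.73. Of 12 stemness and aldehyde dehydrogenase genes 3 rose and 5 fell (3 and 6 adjusted over the list alone; adjusted p = 0.216), among them CD44, which rose 2.41-fold to 68.1 ± 2.22, SOX4, which rose 1.69-fold, and NES and ALDH3A2, which fell 3.07-fold and 2.00-fold.

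**Figure D3:**
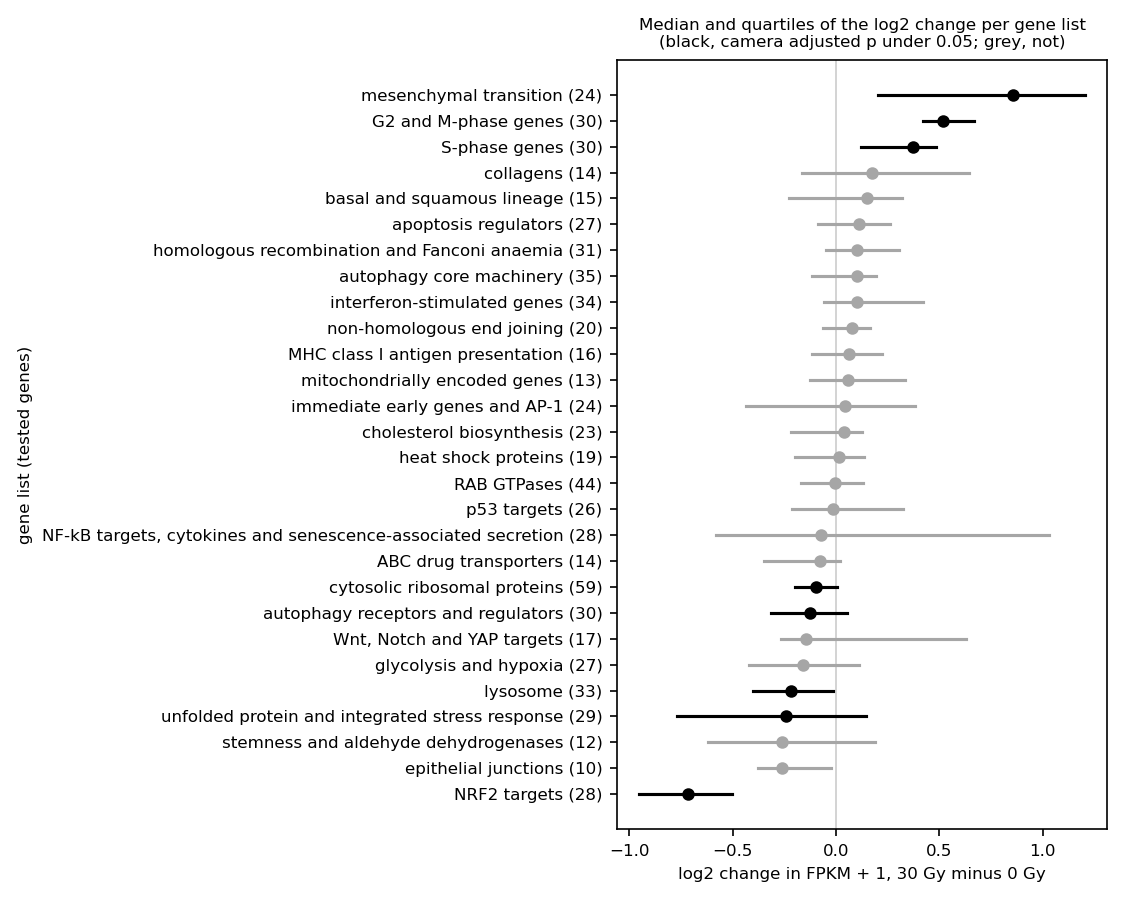
Median log2 change (dot) and quartiles (line) of the tested genes of each list, 30 Gy minus 0 Gy (x axis, log2 of FPKM + 1), with the lists and their tested genes on the y axis. The 8 lists drawn in black passed camera at the preset correlation, with NRF2 targets lowest at -0.72 and mesenchymal transition highest at 0.85.

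Cytosolic ribosomal protein genes had a slightly lower median, and whether the list passed depended on the test. Of 59 tested genes 0 rose and 4 fell (0 and 3 adjusted over the list alone), RPS13, RPS4X, RPL22 and RPL4; RPS13, in the chromosome 11 stretch, fell from 225 ± 46.2 to 95.4 ± 14.5 FPKM. The median was -0.10 and the camera adjusted p 0.0315 at the preset correlation of 0.01. The estimated correlation of the list was 0.706, which gave a camera adjusted p of 0.883, and fry gave an adjusted p of 0.494. With a replicate block the camera adjusted p was 0.0515. Without the first 0 Gy library the median was 0.03, and without the first 30 Gy library it was -0.07. Mitochondrially encoded genes took 6.22% and 6.11% of the reads in the 0 Gy libraries and 6.63% and 7.13% in the 30 Gy libraries. Of their 13 genes MT-ND6, MT-ND5 and MT-CO1 rose by 0.47, 0.44 and 0.34 on the log2 scale and 0 fell, also adjusted over the list alone (adjusted p = 0.388).

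Few markers of other cell types passed the expression filter. Of 18 haematopoietic genes 1 passed the expression filter, LCP1, which rose from 0.569 ± 0.0176 to 1.73 ± 0.127 FPKM, and none of 10 endothelial or 10 neuroendocrine genes did. Of 10 fibroblast genes COL1A1 (62.2 ± 0.182 and 72.9 ± 4.76) and PDGFRB (0.685 ± 0.0460 and 1.48 ± 0.0347) were tested and did not pass, but 2 rose adjusted over the list alone. Of 12 lung adenocarcinoma and alveolar genes MUC1 was tested (1.11 ± 0.0708 and 0.964 ± 0.0823) and did not pass. Of 11 genes of liver, kidney and cervical cell lines LHX1 rose from 2.83 ± 0.443 to 7.89 ± 0.0831 and AFP from 1.41 ± 0.178 to 2.53 ± 0.225, also adjusted over the list alone.

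Position along the chromosomes was examined after the values were seen. On chromosome 11, 31 consecutive protein-coding genes with a mean FPKM of at least 3, from PARVA to MUC15 (11:12377185-26572233), were all lower at 30 Gy. The quartiles of their FPKM ratio were 0.437 and 0.555, and between any 0 Gy and any 30 Gy library the median ratio lay between 0.482 and 0.520. COPB1, a coatomer subunit, stood at a mean of 95.8 and 47.9 FPKM, HTATIP2 at 131 and 59.0, and TSG101, of the ESCRT machinery, at 44.2 and 20.7. The 25 genes after its end had a median ratio of 0.716 and the 25 before its start 1.11, so lower expression was not confined to the stretch. The longest run of 1 sign lay on chromosome 20 from 31.5 to 35.4 Mb, where 37 consecutive genes, among them TPX2 and BCL2L1, were higher with a median ratio of 1.26; shuffled gene orders held at most 21 in a row. Without the 41 tested genes of the chromosome 11 stretch 2600 genes were called.

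**Figure D4:**
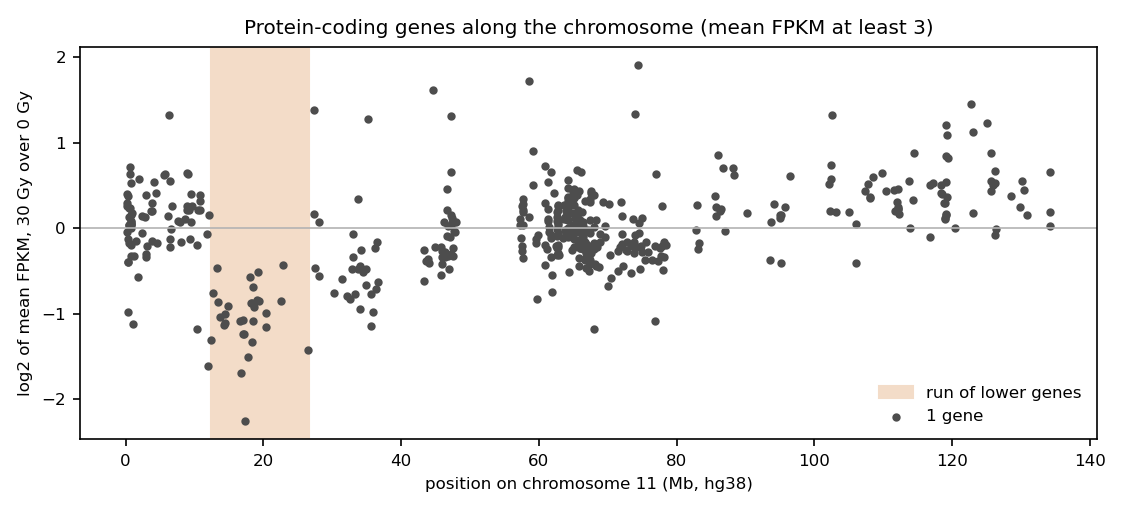
log2 of the ratio of mean FPKM, 30 Gy over 0 Gy (y axis), of protein-coding genes with a mean FPKM of at least 3 by their start on chromosome 11 (x axis, Mb, hg38); each point is 1 gene. The shaded stretch from 12.4 to 26.6 Mb holds the 31 consecutive genes that are lower at 30 Gy, with FPKM ratios of 0.209 to 0.741.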

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

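No gene that was named by the rule and passed in the main test changed direction in any alternative that tested it. Genes named outside the rule were not followed, apart from voom. Among the lists that passed, only the ribosomal protein list changed direction. The alternatives chosen after the data were seen are voom, the removal of GC and length trends, protein-coding genes alone, rescaling without mitochondrial genes, and leaving out the chromosome 11 stretch. Genes changed between 30 Gy and 0 Gy, 2654 in the main test, numbered 604 with no filter (352 higher, 252 lower, 203 at least 2-fold; 30687 genes tested) and 4231 with voom (2182 lower, 558 at least 2-fold). They numbered 3851 of 11125 among protein-coding genes alone and 3482 with the GC and length trends removed. Genes changed at least 2-fold between 30 Gy and 0 Gy, 347 in the main test, numbered 203 at a filter of FPKM 5 and 227 among protein-coding genes alone. Leaving out each library in turn gave 0 to 898 genes changed between 30 Gy and 0 Gy, 0 to 484 among genes higher in 30 Gy, 0 to 414 among genes lower in 30 Gy and 0 to 310 among genes changed at least 2-fold between 30 Gy and 0 Gy; such fits leave a lone library that is assumed to vary like the other group. RAB39B kept its sign but not its call with no filter (-0.803) and with each library left out (-0.889 to -0.718). The scalings, with or without mitochondrial genes, and the eBayes settings gave 2255 to 2875 genes, with 49.5% to 56.1% of them higher against 54.3%. A replicate block, for numbers that show no pairing (correlation of replicate deviations -0.0263), gave 1926 genes. Of the gene lists, 8 passed in the main test, 0 with an estimated correlation and 15 with fry. The ribosomal protein list (list: cytosolic ribosomal proteins) had a median of 0.0308 without the first 0 Gy library, against -0.216 to -0.0683 without the others; the cause was not tested. The similarity of replicates, the mean r within groups less that between groups, was 0.0256 and became 0.0351 with a pseudocount of 0.1 and 0.0435 at a filter of FPKM 5. Calls of other named genes ended for 123 without either 0 Gy library, for 45 and 43 without the first and second 30 Gy library, for 51 with no filter, for 14 with the replicate block and for 10 with eBayes without trend. For a gene the length of KRT6A, 3 reads equal 0.0589 to 0.0644 FPKM.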

Other observations

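Further gene families were looked at after the results were seen. Protein-coding genes were grouped by the letters that open their symbols, which gave 143 families of at least 10 tested genes, and each was tested for rises and for falls by a one-sided Fisher's exact test, adjusted over 286 tests. This test treats genes as independent. Its p-values take no account of genes that vary together and are less certain than they read. Of 12 cytochrome P450 genes (CYP) 7 fell where 1.14 were expected (adjusted p = 0.00999), among them CYP4F11 (2.49-fold lower), CYP4F3 (3.92-fold lower) and CYP27A1 (1.57-fold lower), whereas CYP2S1 rose 4.62-fold; CYP2R1, also lower, lies in the chromosome 11 stretch. Of 28 genes whose symbols open with KIF, nearly all kinesin motors, 11 rose where 3.29 were expected (adjusted p = 0.0260). KIF20A, KIF11, KIF23 and KIF2C are also on the G2 and M-phase list, while KIF14 (1.64-fold), KIF20B (1.67-fold) and KIF3C (1.88-fold) are not. Next to CGB5 and CGB8, CGB7 rose 4.92-fold and LHB 3.36-fold, and next to CST1 the salivary cystatins CST2 and CST4 rose 6.66-fold and 5.34-fold, while CST3, the ubiquitous cystatin C, stood at 43.4 and 49.3 FPKM and did not pass. Reads may be shared among these copies, which was not tested further. For CGB7, voom gave a log2 change of 2.26, but it used the same assignment of reads to copies and cannot settle this.

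The tests of the chromosome 11 stretch against GC content and against copy number were chosen after the stretch was seen, the latter in place of a weaker test of the same kind that gave the same answer; the tests of the other patterns, and of chance order, were chosen before their results. NRF2 target genes were lower in the 30 Gy libraries. A difference in scaling between libraries would move all genes alike, but the median of all tested genes was -0.0007. The list median stayed at -0.73 or lower under median centring, quantile normalization and rescaling to equal sums. These put the median of all genes at -0.0183, -0.01 and -0.0259. Shifts that small could not have brought the list near 0, so the scalings add little to that median. Removing each library's trend on GC content and gene length left the list median at -0.72. Lower NRF2 activity in the 30 Gy cells is a hypothesis that remains open. NFE2L2, which encodes NRF2, stood at 43.8 and 45.3 FPKM and did not pass. KEAP1, its inhibitor, was lower (42.0 and 34.3, limma adjusted p = 0.0311). These are RNA levels and cannot decide the question, as NRF2 protein was not measured. The dose, the cell line derivation and the culture state of each group are not separated by the design.

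KRT6A had 0 reads in all 4 libraries. Reads lost to the near-identical KRT6B and KRT6C do not account for this, since 86.4% of the 2971 windows of 100 bases in KRT6A's transcripts occur in no other gene, and KRT6B and KRT6C were at 0 as well. A general failure of estimates in the file was not seen either, as 0 of 60 cytosolic ribosomal protein genes were at 0 in any library. That check covers abundant genes and cannot exclude a failure limited to KRT6A or its neighbours. A candidate explanation is that the cells used here do not express KRT6A at a level this depth can detect. KRT5, KRT6B and KRT6C at 0 also leave open whether the cells are of the squamous line the labels name. TP63, the squamous lineage factor, was expressed, at a mean of 4.04 FPKM at 0 Gy and 3.26 at 30 Gy. These genes cannot settle the identity, as no reference profile of the line was compared. Other samples of the study were not analysed here.

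Neighbouring genes changed together along chromosomes: over 25 consecutive genes the largest absolute median log2 change, 1.003 on chromosome 11, was reached in 0% of 1000 shuffled gene orders, whose highest value was 0.378. Removing the GC and length trends left the median of the 31 genes at -0.98. A candidate explanation is fewer DNA copies of the stretch in the 30 Gy cells: 100% of the 12 other genes inside it with at least 20 reads over the 4 libraries that overlap none of the 31 were lower as well, against 51.3% of all genes with as many reads that were outside the scan on other chromosomes. Silencing of the stretch without loss of DNA would lower them too and was not tested. Smaller shifts appeared in 13 windows outside the stretch that passed the 95th percentile of the shuffled orders, among them chromosome 11 from 119.02 to 130.14 Mb (median FPKM ratio 1.44), chromosome 11 from 34.05 to 45.92 Mb (0.754) and chromosome 20 from 35.7 to 38.95 Mb (1.38).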
